A study of Mus musculus with 18 samples.

How the data were processed

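RNA was measured in 18 libraries from cultured mouse cells. B16F10 melanoma and E0771 mammary tumour cells carried an empty pRetrox vector (control), MRTFA or MRTFB, induced with doxycycline at 500 ng/mL for 48 h, in 6 groups of 3 replicates. Samples were grouped by the line, transgene and replicate number in their labels, and no column was left without a sample. Per the submitters' processing notes, reads were trimmed with cutadapt 1.6, aligned to mm10 with STAR 2.5.0a, counted per gene with HTSeq 0.5.3 and scaled with DESeq, whose version is not given in the sources used here. Nor are the annotation release, strandedness and counting mode. The deposited values are a signal per gene that the authors obtained by dividing reads by the DESeq size factor of the library. In every library each value was a whole multiple of its smallest step within 0.001 read, so whole reads were recovered. Size factors recomputed from them differed from the steps by at most 0.0048%. The table holds 18909 genes, each with at least 15 reads summed over the libraries. Identifiers were looked up in GENCODE M21 (GRCm38), which had 18827 of them and lacked 82; 14615 were protein coding. The file uses older symbols, so Mrtfa is Mkl1, Mrtfb is Mkl2, Ccn1 is Cyr61 and Ccn2 is Ctgf.

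Recovered reads per library ranged from 27607055 to 37116655. A count of 0 in a library allows up to 3 reads, which is 0.081 to 0.109 CPM (reads scaled to a common library size) at these depths. For genes at 0 reads in a group, a fold was computed against 3 reads over that group, and for 1 to 3 reads the ratio is given with an exact binomial 95% interval. The reads carry no molecular identifiers, so intervals and limits cover counting error only. No pair of libraries within a group was a duplicate, and pairs across groups were not compared in this way. Over genes with at least 20 reads, chi-square per degree of freedom between libraries of a group was 11.7 to 59.2.

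Genes were tested with limma 3.58.1 (trend) on log2 of the scaled value plus 1, among genes with a value of at least 10 in at least 3 fitted libraries. Each line's 9 libraries were fitted together for MRTFA against control, MRTFB against control and MRTFB against MRTFA, and all 18 for the difference between lines in each effect (E0771 minus B16F10). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All p-values are two-sided. Whether equal replicate numbers belong together was checked by correlating, across genes, the deviations of equal-numbered libraries from their group means. Over the replicates these correlations were 0.375 to 0.584 for MRTFA and 0.429 to 0.499 for MRTFB in B16F10, 0.525 to 0.588 for MRTFB in E0771, and 0.408 to 0.644 and 0.124 to 0.473 for MRTFB against MRTFA in B16F10 and E0771. These comparisons were read as paired, and values with replicate number as a block are given beside the unblocked ones where they change a call. For MRTFA in E0771 (0.079 to 0.522) and the line differences (−0.084 to 0.478 and 0.021 to 0.457) the numbers were not read as pairs, because the lowest values were small. That choice is open, since the same E0771 MRTFA libraries were read as paired when set against MRTFB, at a lowest value of 0.124. For MRTFA in E0771 only replicate 1 was low (0.079), against 0.473 and 0.522 for replicates 2 and 3. The line differences include pairs across lines, and within lines the MRTFB difference had 0.339 to 0.457. Blocked list calls that differ for MRTFA in E0771 are therefore given too. The labels do not say what the numbers stand for.

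Gene lists were written from general knowledge before the data were examined. There were 23 with 519 members, 479 of them in the table. They cover MRTF-SRF cytoskeleton targets, smooth muscle, striated muscle, immediate early genes, YAP-TAZ targets, integrins, extracellular matrix, activating or adhesion ligands of NK and T cells, MHC class I, inhibitory ligands and resistance, interferon response, melanocyte and mammary genes, mesenchymal transition, cell cycle, cholesterol synthesis, p53 targets, ATF4 targets, glycolysis and hypoxia, ribosomal proteins, and immune and endothelial or fibroblast markers. The results of 1 list are not reported here. Some genes belong to several lists: Fas is both an activating-ligand list member and a p53 target. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over all lists and the 4 comparisons with control. Camera with an estimated correlation and fry were run as alternatives. The named genes followed a rule fixed before the data were examined. It took the transgenes, 12 anchor genes, the 8 largest increases and 6 largest decreases per comparison with control among called genes with non-overlapping values and a mean of at least 50, up to 4 members per list by adjusted p, and 5 genes each way for the other comparisons. Predicted and clone-named genes were left out.

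The tests were tested on simulated data with the groups' own spread, 100 genes changed 2-fold and 100 changed 4-fold. Only genes with a mean of at least 50 were changed. Each gene was drawn on its own, without deviations common to equal replicate numbers. The shares recovered therefore do not carry over to weaker genes, or to single genes that vary widely between replicates. Of the 2-fold changes limma recovered 85% and 88% for MRTFA and MRTFB in B16F10 and 78% and 87% in E0771, and of the 4-fold changes 98 to 100%. False calls made up 4.2 to 6.8% of calls. For the line differences 58% and 67% of 2-fold changes were recovered for MRTFA and MRTFB, with 9.6% and 3.7% false calls. Overlaps between the comparisons of a line were set against 100 simulations in which only the control was shared. They held no transgene effect, and deviations common to equal replicate numbers were not simulated.

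Alternatives changed 1 choice at a time: pseudocounts of 0.5 and 5, no filter, a minimum of 50, TMM or upper-quartile scaling, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the replicate block, all 18 libraries in each fit, only the libraries compared, and each library left out. Added after the data were seen were edgeR with the block and fits without every group's replicate 1 or replicate 3. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Variant calls, splicing and the construct's own sequence were not analysed here.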

Results

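MRTFA and MRTFB are coactivators of serum response factor (SRF). They leave the cytoplasm when actin polymerises and switch on genes of the actin cytoskeleton and of muscle contraction. The comparisons ask which genes changed when either protein was expressed for 48 h with doxycycline at 500 ng/mL in mouse B16F10 melanoma or E0771 mammary tumour cells, against the empty pRetrox control of the same line. Each of the 6 groups had 3 libraries. The labels do not say whether the replicates were separate cultures, so they may be technical, and every test measures only the spread between these libraries. Values are scaled reads as mean ± SD (n = 3). Fold changes are limma's fitted log2 values with their SE unless a ratio of means is named. The actin genes Acta1, Acta2, Actc1, Actg2, Actb and Actg1, and other families of close paralogs such as Gstp2 and Tmsb4x, may share reads, because the counting mode and strandedness are not given in the sources used here.

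Each transgene's own gene was called higher in E0771 only, and a difference between the lines was shown for Mkl1 (3.12, adjusted p = 9.84e-07) but not for Mkl2 (0.34, 95% interval −0.04 to 0.72, adjusted p = 0.96). Mkl1 (ENSMUSG00000042292.16, which encodes MRTFA; GRCm38 chromosome 15, 81012281 to 81190757) had 13730 ± 2454 scaled reads in E0771 MRTFA libraries against 1349 ± 202 in controls. That was a log2 rise of 3.34 (SE 0.19, adjusted p = 4.68e-07). Mkl2 (ENSMUSG00000009569.14, which encodes MRTFB; chromosome 16, 13256481 to 13417529) had 2158 ± 87.9 in E0771 MRTFB libraries against 1344 ± 106, a rise of 0.69 (SE 0.10, adjusted p = 0.0306). The Mkl2 call was lost without any single one of the 6 libraries. Its log2 values were then 0.72, 0.67 and 0.67 without MRTFB replicates 1, 2 and 3, and 0.63, 0.69 and 0.74 without control replicates 1, 2 and 3. In B16F10 libraries labelled MRTFA, Mkl1 had 1205 ± 266 against 1015 ± 83.3, a log2 value of 0.22 (95% interval −0.18 to 0.63, adjusted p = 0.856), so a difference above 1.54-fold lay outside the interval. In B16F10 libraries labelled MRTFB, Mkl2 had 1886 ± 128 against 1501 ± 330, a log2 value of 0.35 (95% interval 0.03 to 0.67, adjusted p = 0.503). Neither gene was called in the group of the other transgene.

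**Figure D1:**
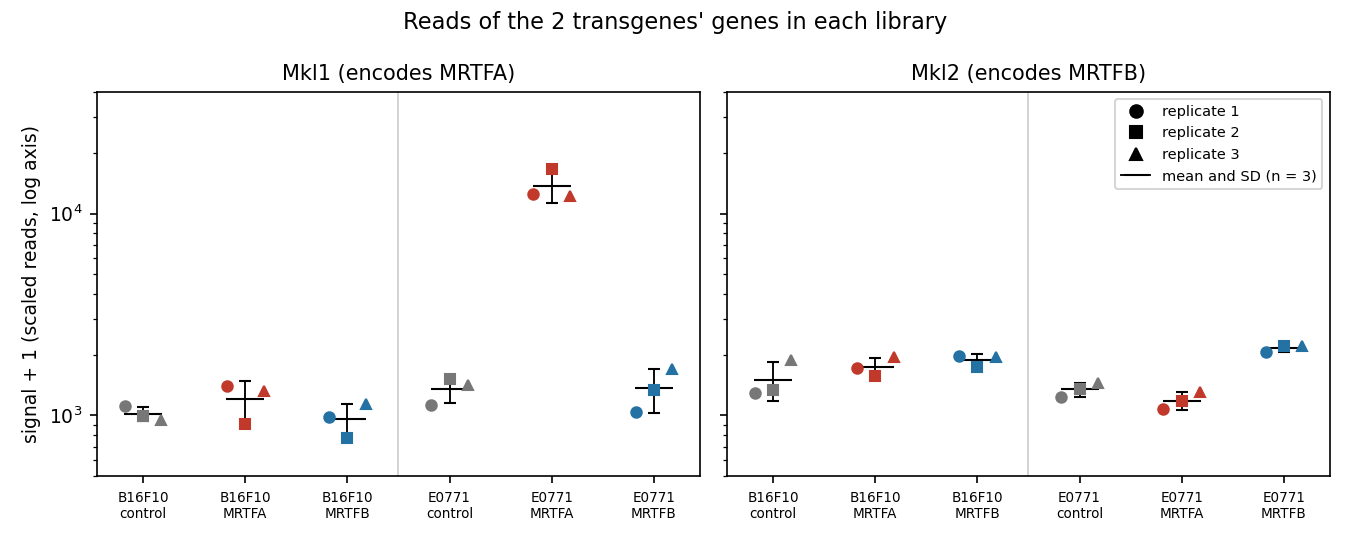
Scaled reads plus 1 (log axis) of Mkl1 and Mkl2 in each of the 18 libraries, by line and transgene; the horizontal bar and whiskers give mean and SD of 3 libraries. Mkl1 averaged 13730 in E0771 MRTFA and 1205 in the B16F10 libraries labelled MRTFA, and Mkl2 averaged 2158 in E0771 MRTFB.

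With MRTFA in E0771 cells, smooth and striated muscle genes rose, some from an expressed level, such as Acta2, and some from near silence, such as Actc1. Smooth muscle alpha-actin, Acta2 (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255590), went from 19750 ± 3804 to 735300 ± 70890 scaled reads, a ratio of 37.2 (log2 5.23, SE 0.16, adjusted p = 7.63e-09), and took 2.19% of all reads. Cardiac actin Actc1 (ENSMUSG00000068614.7, chromosome 2, 114047282 to 114053548) went from 6.31 ± 4.12 to 79240 ± 29930 (log2 13.53, SE 0.47, adjusted p = 2.01e-08). The actin-bundling Tagln (ENSMUSG00000032085.4, chromosome 9, 45929619 to 45936058) rose from 383 ± 109 to 37920 ± 12770 (log2 6.61, adjusted p = 5.73e-08). The myosin light chain Myl9 rose by 6.11 on the log2 scale (adjusted p = 6.19e-09) and calponin Cnn1 by 6.07. The LIM-domain gene Fhl1 (ENSMUSG00000023092.16, chromosome X, 56731787 to 56793346) went from 2.64 ± 2.12 to 7087 ± 973 (log2 11.08). For genes with 0 to 3 control reads in all, the fitted value depends on the pseudocount, so reads were compared directly. Myosin heavy chain Myh13 was at least 1432-fold higher and the protease gene Prss46 at least 1506-fold higher, against a limit of 3 reads over the control group. The actin nucleator Cobl had 1 control read and a ratio of 6422 (95% counting interval 1152 to 253700). The decoy receptor Il1r2 (ratio 2401, interval 821.4 to 11650) and the keratin Krt20 (ratio 2235, interval 764.5 to 10840) had 3 each. These intervals and limits cover counting error only.

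Contractile and cytoskeletal lists moved almost as a block in E0771 MRTFA cells. In the smooth muscle list 16 of 16 tested genes rose and none fell (median log2 5.68), among them the myosin light chain kinase Mylk (8.23) and Actg2 (8.58). Camera, limma's list test, gave adjusted p = 1.68e-16, and adjusted p = 0.0738 with an estimated correlation. In the MRTF-SRF actin cytoskeleton list 29 of 30 rose (median 1.85), with vinculin Vcl at 2.57, Actb at 1.49, Actg1 at 1.41, Fhl2 at 2.02, Tpm1 at 2.53, Csrp1 at 3.53 and Srf itself at 2.19 (camera adjusted p = 5.98e-19, adjusted p = 0.298 with an estimated correlation). The striated muscle list had 11 of 13 higher (median 3.61; adjusted p = 2.95e-07, adjusted p = 0.179 with an estimated correlation). Fry, the other alternative, gave adjusted p = 2.8e-06, 0.00015 and 8.6e-05 for the 3 lists in this order. In this comparison it kept every list called by camera except ribosomal proteins (0.116). Here and in what follows, a list given without a count adjusted over the list alone had the same count on that basis.

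**Figure D2:**
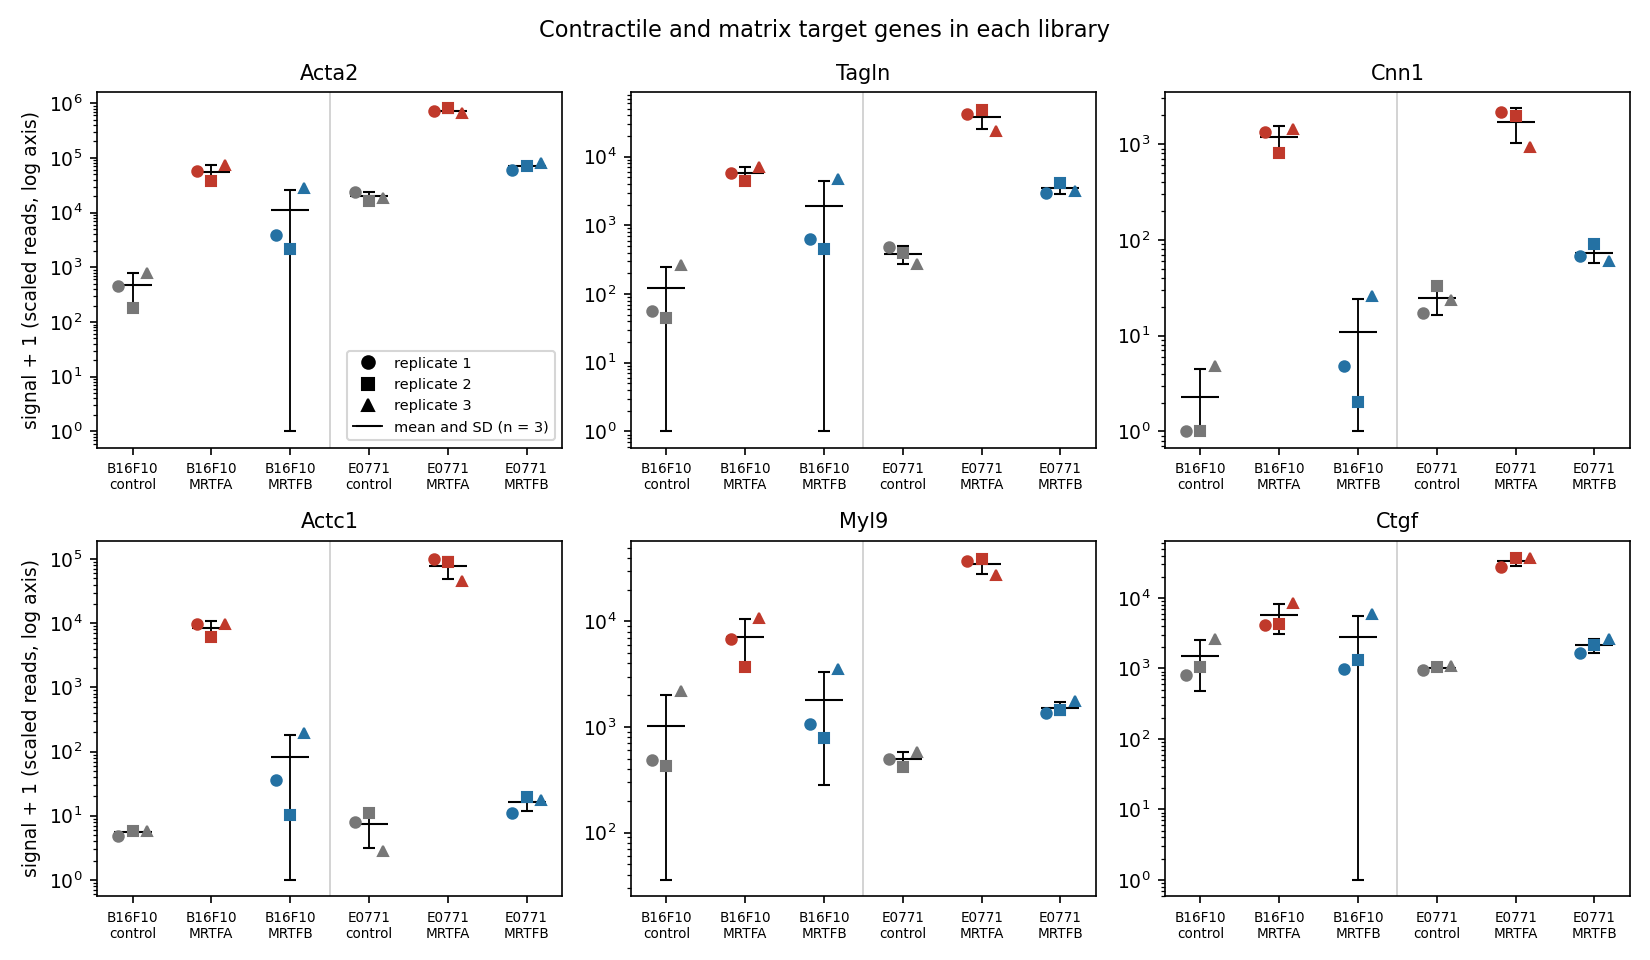
Scaled reads plus 1 (log axis) of Acta2, Tagln, Cnn1, Actc1, Myl9 and Ctgf in each library; bars and whiskers give mean and SD of 3 libraries, and a whisker stops at 1 where the SD exceeds the mean. Acta2 averaged 735300 in E0771 MRTFA, 56340 in B16F10 MRTFA and 479 in the B16F10 control.

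Adhesion, matrix and growth-response genes also rose with MRTFA in E0771. The fibronectin receptor subunit Itga5 went from 4001 ± 130 to 37900 ± 3042 (log2 3.24, adjusted p = 4.31e-09) and the collagen receptor subunit Itga1 from 465 ± 65.5 to 8897 ± 928 (4.26). In the integrin and focal adhesion list 13 of 22 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.93; camera adjusted p = 7.33e-05, adjusted p = 0.154 with an estimated correlation). In the extracellular matrix list 11 of 21 rose and none fell (11 adjusted over the list alone; median 1.08; adjusted p = 0.000103, adjusted p = 0.385 with an estimated correlation), led by fibrillin Fbn1 (7.80) and tenascin Tnc (4.59). Connective tissue growth factor Ctgf (Ccn2; chromosome 10, 24595442 to 24598683) went from 1028 ± 59.2 to 33500 ± 5132 (log2 5.02, adjusted p = 9.41e-09). Of 18 YAP-TAZ targets 12 rose, such as Ctgf, Cyr61 (2.20) and Ankrd1 (3.61), and 3 fell, such as Myof (−0.75); 14 and 3 changed adjusted over the list alone. The median was 0.71 (camera adjusted p = 0.00074, adjusted p = 0.385 with an estimated correlation). Of 19 immediate early genes 12 rose and 2 fell (13 and 2 adjusted over the list alone), with Egr1 at 3.85, Egr3 at 4.96 and Fos at 3.23. Their median was 1.65 (adjusted p = 0.00318, adjusted p = 0.633 with an estimated correlation).

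Genes that tumour cells use to meet cytotoxic lymphocytes moved both ways with MRTFA in E0771, as did genes at large. Over all 13189 tested genes 2677 were called higher and 2387 lower, a share close to that of the inhibitory genes below. The death receptor Fas (ENSMUSG00000024778.12, chromosome 19, 34290666 to 34327772) went from 46.0 ± 13.0 to 968 ± 87.9 (log2 4.40, adjusted p = 2.77e-07), and the TRAIL receptor Tnfrsf10b rose by 1.90. Pvr, a ligand of the activating receptor DNAM-1, rose from 3408 ± 840 to 8858 ± 1647 (1.39, adjusted p = 0.000551) and the NKG2D ligand Ulbp1 rose by 1.33. In that list of activating and adhesion ligands 4 of 12 rose and none fell (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.239, fry adjusted p = 0.0249). Among inhibitory ligands and resistance genes 3 of 16 rose, such as Bcl2 (1.93), and 3 fell: Lgals3 (−1.40), Cd276 (−0.99) and Nt5e (−0.81). Camera gave adjusted p = 0.646, and the counts were 3 and 3 adjusted over the list alone. In MHC class I presentation 7 of 17 rose, such as Nlrc5 (2.38), Tapbp (1.80) and Tap2 (1.78), and 2 fell, such as Canx (−0.57). The median was 0.83 with camera adjusted p = 0.0558, and 0.803 with an estimated correlation. With the replicate block 13 rose and 2 fell (camera adjusted p = 0.000834). Of 24 interferon response genes 2 rose, Gbp2 (3.98) and Irf1 (0.91), while Ifit3 (1.44, adjusted p = 0.112) and Cxcl10 (1.37, adjusted p = 0.125) were not called. The list had camera adjusted p = 0.0965, and 0.892 with an estimated correlation. With the replicate block 15 rose and none fell (camera adjusted p = 0.000125). Without control replicate 3, Cxcl10 was called at 1.92.

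Epithelial, mesenchymal and pigment genes moved both ways with MRTFA in E0771. Mammary epithelial genes had 7 of 11 higher, such as Krt7 (1.91), Krt8 (1.22) and Lcn2 (3.88), and 1 lower (7 and 2 adjusted over the list alone; median 1.22; camera adjusted p = 0.0702, fry adjusted p = 0.0158). Mesenchymal transition genes had 8 of 18 higher, such as Mmp14 (1.61), Tgfb2 (1.45) and Zeb1 (1.05), and 1 lower, vimentin Vim (−0.90), with camera adjusted p = 0.0596. Camera gave 0.0272 with the replicate block and 0.48 with an estimated correlation, and fry gave 0.00453. Of 7 tested melanocyte genes Rab27a rose (4.56) while Mitf (−0.95) and Met (−0.82) fell; the median was −0.04, the mean 0.49 and the test pointed down (adjusted p = 0.818). Of 5 immune cell markers Coro1a rose (5.37) and Lyz2 fell (−0.69, adjusted p = 0.0395), with a median of −0.12, a mean of 0.96 and an upward test (adjusted p = 0.818). The Lyz2 call was lost without MRTFA replicates 1, 2 or 3 (−0.75, −0.57, −0.75) or control replicates 1 or 3 (−0.67, −0.47). Of 5 endothelial and fibroblast markers Col6a3 rose (2.02) and Pdgfra (−1.33) and Egfl7 (−0.86) fell (camera adjusted p = 0.321, fry adjusted p = 0.0249, down).

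Many proliferation and ribosomal genes were lower with MRTFA in E0771. In the cell cycle list 17 of 24 fell and 1 rose (20 and 1 adjusted over the list alone; median −0.43), with Mcm6 at −0.86, Pcna at −0.71, Rrm2 at −0.67 and Ccnd1 at −0.55. Camera gave adjusted p = 1.67e-06, and adjusted p = 0.152 with an estimated correlation. Of 24 ribosomal proteins 11 fell and none rose, such as Rps4x (−0.51) and Rpl3 (−0.42); the median was −0.24 (adjusted p = 0.00505, adjusted p = 0.623 with an estimated correlation). p53 targets had 9 of 20 higher, such as Pmaip1 (2.5) and Phlda3 (0.97), and none lower (median 0.05; adjusted p = 0.0318, adjusted p = 0.623 with an estimated correlation). Glycolysis and hypoxia genes had 7 higher and 4 lower of 22 (adjusted p = 0.646); adrenomedullin Adm went from 2149 ± 386 to 20380 ± 4700 (3.24), whereas Pdk1 was at −0.89. Cholesterol synthesis had 2 higher and 3 lower of 22 (1 and 3 adjusted over the list alone; adjusted p = 0.446), with Sqle at −0.64 and Sc5d at −0.52. The ATF4 stress list had 2 higher, such as Nupr1 (0.70), and 2 lower, Ddit4 (−1.12) and Psat1 (−0.52), of 22 (1 and 2 adjusted over the list alone); its median of 0.01 and mean of 0.01 were above 0 while the test pointed down (adjusted p = 0.646). The largest decreases outside the lists were smaller than the increases. The protease-activated receptor F2rl1 (ENSMUSG00000021678.8, chromosome 13, 95511732 to 95525227) went from 1949 ± 169 to 497 ± 24.0 (log2 −1.97, adjusted p = 2.77e-07) and cytidine deaminase Cda from 704 ± 7.24 to 192 ± 14.0 (−1.87). Tex101 fell by 2.87 (adjusted p = 0.00116), Rbp7 by 1.93, Sema5a by 1.84 and Plek2 by 1.78.

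By limma, 5064 of 13189 tested genes changed with MRTFA in E0771, 2677 higher and 2387 lower. Which direction held more genes depended on the setting. Upper-quartile scaling gave 2532 higher and 2753 lower, and a minimum of 50 gave 2191 and 2353. At least 2-fold changes were mostly increases, with 1499 genes higher and 161 lower. edgeR called 4908. Acta1, which took 37000 ± 7941 scaled reads against 28.9 ± 4.47, Actc1 and the other genes named as largest changes kept their calls without any single library. The count dropped to 3260 without MRTFA replicate 2.

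With MRTFB in E0771, a much shorter set of the same contractile genes rose. Mkl2 rose by 0.69 in these libraries, whereas Mkl1 rose by 3.34 in the E0771 MRTFA libraries. A weaker action of MRTFB therefore cannot be told apart from a lower dose. Acta2 went from 19750 ± 3804 to 69950 ± 10040, a ratio of 3.54 (log2 1.83, SE 0.16, adjusted p = 0.00116), and Tagln from 383 ± 109 to 3439 ± 604 (3.19, adjusted p = 0.00116). Skeletal actin Acta1 (ENSMUSG00000031972.4, chromosome 8, 123891769 to 123894751) went from 28.9 ± 4.47 to 385 ± 216 (3.54, adjusted p = 0.00366). Leiomodin Lmod1 (ENSMUSG00000048096.7, chromosome 1, 135324807 to 135368065), an actin nucleator of smooth muscle, went from 31.1 ± 8.25 to 193 ± 97.9 (2.51, adjusted p = 0.0102). Fas rose from 46.0 ± 13.0 to 145 ± 30.6 (1.65, adjusted p = 0.025). Myl9 (1.61), Actg2 (1.91), Krt7 (1.18) and Ctgf (1.04, adjusted p = 0.038) were also called. In all 19 of 13189 genes were called by limma, 18 higher and 1 lower, and 13 by edgeR. With replicate number as a block, which the pairing check allowed for this comparison, 33 were called (32 higher, 1 lower), Cyr61 among them (0.89; blocked adjusted p = 0.00244, unblocked 0.561). Cnn1 (1.61, adjusted p = 0.259), Vcl (0.61), Actb (0.52), Actg1 (0.56), Srf (0.18), Tpm1 (0.18) and Fhl2 (0.10) were not called. Acta2, Tagln, Acta1, Actg2 and Myl9 kept their calls without any single library, while Lmod1 lost its call without control replicate 1 (2.48). Krt7 lost its call without any single one of the 6 libraries, at values of 1.05 to 1.26. Fas lost its call without MRTFB replicates 1 or 3 (1.49, 1.68) or control replicates 1 or 2 (1.59, 1.5), and Ctgf without MRTFB replicates 2 or 3 (1.02, 0.89) or control replicates 1, 2 or 3 (0.99, 1.04, 1.07). The count was 10, 11 and 10 without MRTFB replicates 1, 2 and 3, and 7 and 8 without control replicates 1 and 2.

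The smooth muscle list with MRTFB in E0771 was the single camera call, over all lists and comparisons, that also passed with an estimated correlation. Of its 16 genes 6 rose and none fell (10 adjusted over the list alone; median 1.29; camera adjusted p = 8.43e-42, adjusted p = 0.0235 with an estimated correlation). Fry gave adjusted p = 0.00121 for this list and 0.209 for the cytoskeleton list. In the cytoskeleton list none of 30 was called by limma over all genes, 11 rose adjusted over the list alone and 2 with the block (median 0.31; adjusted p = 8.75e-21, adjusted p = 0.293 with an estimated correlation). Csrp1 stood at 1.09 with adjusted p = 0.0596 (blocked 0.0141), and passed without control replicate 3 (1.28). Striated muscle had 1 of 13 higher (adjusted p = 2.78e-05, adjusted p = 0.293 with an estimated correlation). Extracellular matrix had none of 21 called, 3 adjusted over the list alone and 2 with the block (adjusted p = 8.60e-09, adjusted p = 0.179 with an estimated correlation): thrombospondin Thbs1 was at 1.83 (adjusted p = 0.16, blocked 0.0228; called without control replicate 3, at 2.22) and Tnc at 0.58 (adjusted p = 0.494, blocked 0.0228). YAP-TAZ targets had 1 of 18 higher, 3 adjusted over the list alone (adjusted p = 0.000103, adjusted p = 0.298 with an estimated correlation); the tissue factor gene F3 was at 0.64 (adjusted p = 0.0598, blocked 0.0107). Upward calls were also lost for the p53 list (1 of 20 higher, 2 adjusted over the list alone; adjusted p = 0.00124, adjusted p = 0.48 with an estimated correlation) and for cholesterol synthesis (0 of 22; median 0.16; adjusted p = 5.55e-05, adjusted p = 0.623 with an estimated correlation). So were those of the activating ligands (1 of 12, Fas; adjusted p = 0.0218, adjusted p = 0.623 with an estimated correlation) and of mammary genes (1 of 11, Krt7; adjusted p = 0.0439, blocked 0.0554, adjusted p = 0.678 with an estimated correlation). Ribosomal proteins pointed down (0 of 24; median −0.06; adjusted p = 0.0424, blocked 0.0564, adjusted p = 0.704 with an estimated correlation). Interferon genes were called up only with the block (0 of 24 genes; blocked adjusted p = 0.00378, unblocked 0.303, unblocked with an estimated correlation 0.942).

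Other lists were not called with MRTFB in E0771, and limma called none of their genes. The adjusted p was 0.142 for immediate early genes, 0.0643 for integrins, 0.809 for MHC class I, 0.0674 for inhibitory ligands and 0.131 for melanocyte genes. It was 0.401 for mesenchymal genes, 0.0965 for the cell cycle, 0.39 for ATF4 targets, 0.595 for glycolysis, 0.168 for immune markers (1 of 5 higher adjusted over the list alone) and 0.757 for endothelial and fibroblast markers. Over all genes of this comparison 335 had an unadjusted p under 0.05.

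In B16F10 libraries labelled MRTFA the largest increases were again actin and smooth muscle genes, several of them from near silence in the control. Actc1 went from 4.50 ± 0.564 to 8583 ± 2112 scaled reads (log2 10.58, SE 0.80, adjusted p = 0.00013). Actg2 (ENSMUSG00000059430.14, chromosome 6, 83512905 to 83536265) went from 30.0 ± 26.3 to 25250 ± 6503 (9.97, adjusted p = 0.000232) and Acta1 from 9.60 ± 6.64 to 8666 ± 3148 (9.78). Smooth muscle myosin Myh11 (ENSMUSG00000018830.8, chromosome 16, 14194535 to 14291372) went from 1.93 ± 0.983 to 2136 ± 656 (9.51, adjusted p = 0.00012). Calponin Cnn1 (ENSMUSG00000001349.4, chromosome 9, 22099216 to 22109630) went from 1.27 ± 2.20, 4 reads in all, to 1187 ± 341 (9.41). The paired receptor gene Pilra had 1 control read and a ratio of 2062 (95% counting interval 369.7 to 81490), and the potassium channel subunit Kcnmb1 had 3 and a ratio of 396.3 (135.3 to 1925). Acta2 went from 479 ± 311 to 56340 ± 17910 (7.07, SE 0.83, adjusted p = 0.00133) and Tagln from 122 ± 125 to 5734 ± 1280 (6.0, adjusted p = 0.00429; call lost without MRTFA replicate 1, at 5.98). Vcl was called at 1.05 (adjusted p = 0.0167), a call lost without MRTFA replicates 1 or 3 (1.02, 0.90) or control replicates 1 or 2 (0.97, 1.01). Tpm1 was called at 0.80 (adjusted p = 0.00747), a call lost without MRTFA replicates 1 or 3 (0.81, 0.70). Myl9 (3.08, adjusted p = 0.0683, blocked 1.23e-05) was not called, except without control replicate 3 (3.83). Ctgf (2.03, adjusted p = 0.258, blocked 0.000243), Cyr61 (0.83, adjusted p = 0.584, blocked 0.000433), Actg1 (0.57, adjusted p = 0.0671, blocked 0.0012) and Actb (0.41, adjusted p = 0.352, blocked 0.024) passed only with the replicate block. Srf (0.42, adjusted p = 0.458) and Fhl2 (1.80, adjusted p = 0.454) did not pass.

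Decreases in these libraries were few. The homeobox gene Rhox5 had 996 ± 224 against 4963 ± 2244 (log2 −2.21, adjusted p = 0.00478; lost without MRTFA replicate 1, at −2.21). The pluripotency-associated gene Dppa2 had 44.7 ± 5.25 against 189 ± 50.1 (−2.03, adjusted p = 0.00125), a call kept without any single library. The phosphatase gene Ptpn13 was at −2.17 (adjusted p = 0.00458; lost without MRTFA replicates 1 or 2, at −2.23 and −2.05). Thymosin Tmsb4x had 155 ± 70.7 against 662 ± 98.2 (−2.17, adjusted p = 0.0459). Its call was lost without any 1 library: −1.92, −2.09 and −2.52 without MRTFA replicates 1, 2 and 3, and −2.16, −2.29 and −2.07 without control replicates 1, 2 and 3. Gstp2 (−2.69, adjusted p = 0.0301) and Pir (−2.21, adjusted p = 0.0439) lost theirs without MRTFA replicates 1, 2 or 3 (Gstp2 −2.71, −2.52, −2.83; Pir −2.20, −2.44, −2.0) or control replicates 1 or 2 (Gstp2 −2.14, −2.55; Pir −1.91, −1.96). Limma called 209 of 13517 genes, 181 higher and 28 lower, with 163 higher and 18 lower by at least 2-fold; edgeR called 213. With the replicate block, which the pairing check allowed, 855 were called (538 higher, 317 lower). Every single library moved the count by more than 1.5 times: 37, 63 and 57 without MRTFA replicates 1, 2 and 3, and 133, 131 and 324 without control replicates 1, 2 and 3.

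By list, 11 of 18 smooth muscle genes rose in the B16F10 libraries labelled MRTFA and none fell (13 adjusted over the list alone; median 3.81), such as Mylk (3.23). Camera gave adjusted p = 5.43e-25, and adjusted p = 0.0738 with an estimated correlation. Striated muscle had 6 of 12 higher (7 adjusted over the list alone; median 3.39; adjusted p = 1.08e-11, adjusted p = 0.0738 with an estimated correlation), among them Tnnt3, at least 42.8-fold higher, and Myl1, with a ratio of 220.6 (95% counting interval 39.2 to 8754). In the cytoskeleton list 4 of 30 rose, 10 adjusted over the list alone and 15 with the block (median 0.38; adjusted p = 3.17e-12, adjusted p = 0.48 with an estimated correlation). By fry the smooth and striated muscle lists passed (adjusted p = 0.00304 and 0.00015) and the cytoskeleton list did not (0.198). Extracellular matrix had 2 of 21 higher, Col3a1 (5.86) and Fbn1 (4.53), 5 higher with 1 lower adjusted over the list alone, and 9 higher with 1 lower with the block (adjusted p = 0.000195, adjusted p = 0.639 with an estimated correlation). Integrins had 1 of 23 higher, Itga1 (1.57), 4 adjusted over the list alone and 6 with the block (adjusted p = 7.35e-05, adjusted p = 0.48 with an estimated correlation). YAP-TAZ targets had 1 of 17, Ankrd1 (5.93), a call lost without MRTFA replicates 1 or 2 (5.94, 6.04), and 5 with the block. The YAP-TAZ list had adjusted p = 0.0489, and adjusted p = 0.678 with an estimated correlation.

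Sterol synthesis went the other way in the same libraries. Of 22 cholesterol synthesis genes 1 fell over all genes and 15 fell adjusted over the list alone, as with the block (median −0.32; adjusted p = 3.57e-16, adjusted p = 0.0738 with an estimated correlation, fry adjusted p = 0.00453). The sterol oxidase Msmo1 had 2835 ± 414 against 4144 ± 154 (−0.56, adjusted p = 0.0199), a call lost without MRTFA replicates 1 or 2 (−0.46, −0.54) or control replicates 1 or 2 (−0.57, −0.53). Hmgcs1 (−0.41, adjusted p = 0.0693, blocked 0.00429) and Cyp51 (−0.32, adjusted p = 0.0776, blocked 0.00984) were called only with the block. The cell cycle list pointed down with none of 24 called without the block, and 1 higher and 1 lower with it (median −0.08; adjusted p = 0.0326, adjusted p = 0.48 with an estimated correlation). Interferon genes (median −0.33; adjusted p = 0.0979, blocked 0.00147), ATF4 targets (adjusted p = 0.0965, blocked 0.00917) and ribosomal proteins (adjusted p = 0.0643, blocked 0.0427) were called down only with the block. Unblocked camera with an estimated correlation gave 0.892, 0.803 and 0.876 for them. Among the activating ligands Fas rose from 5.12 ± 3.96 to 55.1 ± 12.1 (3.38, adjusted p = 0.00587), 1 of 12 called (1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.964). Of 9 mammary genes Krt19, at 0 control reads, was at least 23.1-fold higher (3 adjusted over the list alone; list adjusted p = 0.166). The p53 list had 1 of 19 higher, Fas, with a median of −0.01, a mean of 0.19 and an upward test (adjusted p = 0.847). Immediate early genes (adjusted p = 0.935), MHC class I (0.557), inhibitory ligands (0.83), melanocyte genes (0.80), mesenchymal genes (0.686) and glycolysis (0.176) had no gene called without the block, among 1272 genes with an unadjusted p under 0.05 in this comparison. With the block 2 immediate early genes were higher and 2 lower. So were 1 MHC class I and 2 inhibitory genes higher, and 1 mesenchymal and 1 glycolysis gene lower. Immune and endothelial or fibroblast markers had fewer than 5 tested members in B16F10 and were not tested as lists.

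With MRTFB in B16F10 the contractile genes Acta2, Actg2 and Tagln stood above every control library but varied among replicates. Acta2 had 3856, 2146 and 28020 scaled reads in MRTFB replicates 1 to 3 against 462.7, 176.2 and 798 in the controls of the same numbers (log2 3.93, SE 0.83, adjusted p = 0.159, blocked 0.00174). Actg2 had 528, 280.6 and 3772 against 18.3, 11.7 and 60.1 (5.07, adjusted p = 0.0702, blocked 0.00108) and Tagln was at 3.66 (adjusted p = 0.176, blocked 0.0022). Acta1 was at 4.16 (adjusted p = 0.0775, blocked 0.00174), Cnn1 at 1.91 (0.567, blocked 0.0491), Myl9 at 0.92 (0.811, blocked 0.035) and Vcl at 0.40 (0.57, blocked 0.0251). Srf (0.03), Actb (0.10), Actg1 (0.20), Cyr61 (0.09), Ctgf (0.60), Tpm1 (0.15) and Fhl2 (0.87) were not called. Without control replicate 3, Actg2 (5.72), Tagln (4.46) and Acta1 (4.64) passed, and without MRTFB replicate 3 Actg2 passed at 3.97. The genes called were mostly decreases. The junction gene Jup (ENSMUSG00000001552.14, chromosome 11, 100368958 to 100397763), which encodes plakoglobin, had 148 ± 34.4 against 837 ± 256 (−2.47, adjusted p = 0.00793), Dppa2 was at −2.12 (adjusted p = 0.00887) and Rhox5 at −2.16 (adjusted p = 0.0461). Nckap1l was at −3.05, Ptpn13 at −2.05 and Fam178b at −1.96, while the paraneoplastic antigen gene Pnma5 rose by 1.54 (246 ± 43.4 against 85.9 ± 27.7, adjusted p = 0.0473).

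Limma called 17 of 13517 genes with MRTFB in B16F10, 2 higher and 15 lower, and edgeR 16. With the replicate block, which the pairing check allowed, 603 were called (220 higher, 383 lower). The count was 0 without MRTFB replicate 1, MRTFB replicate 2 or control replicate 1, so the calls of Jup, Dppa2, Rhox5, Nckap1l, Ptpn13, Fam178b and Pnma5 were lost there. It was 2 without control replicate 2, where Jup kept its call, and 129 without control replicate 3. Without MRTFB replicate 1, MRTFB replicate 2 and control replicate 1, Jup stood at −2.32, −2.46 and −2.42, Dppa2 at −1.98, −2.22 and −2.10, and Pnma5 at 1.54, 1.66 and 1.46. Without control replicate 2, Dppa2 (−1.94), Nckap1l (−2.81), Rhox5 (−1.88), Ptpn13 (−1.78), Fam178b (−1.78) and Pnma5 (1.36) lost their calls. Without MRTFB replicate 3 so did Rhox5 (−2.13), Ptpn13 (−2.13), Fam178b (−1.94) and Pnma5 (1.41). With all 9 libraries, 1199 genes had an unadjusted p under 0.05.

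Sterol synthesis genes were also lower with MRTFB in B16F10: none of 22 was called by limma over all genes, 13 fell adjusted over the list alone and 12 with the block (median −0.33; camera adjusted p = 1.71e-16, adjusted p = 0.0738 with an estimated correlation, fry adjusted p = 0.00491). Msmo1 was at −0.58 (adjusted p = 0.0755, blocked 0.00529). The list median was −0.32 with MRTFA, and both values rest on the same 3 control libraries. A difference of those controls from both transgene groups therefore cannot be told apart from a response to each transgene. In E0771 the list medians were −0.08 with MRTFA and 0.16 with MRTFB. In the smooth muscle list none of 18 was called, 4 rose adjusted over the list alone and 8 with the block (median 0.67; adjusted p = 0.000425, adjusted p = 0.57 with an estimated correlation). Interferon genes pointed down (0 of 23; median −0.44; adjusted p = 0.01, adjusted p = 0.876 with an estimated correlation). So did glycolysis (0 of 22; median −0.15; adjusted p = 0.00032, adjusted p = 0.48 with an estimated correlation) and immediate early genes (0 of 18, 3 lower adjusted over the list alone; median −0.13; adjusted p = 0.0172, adjusted p = 0.633 with an estimated correlation), in which Klf4 stood at −0.90 (adjusted p = 0.173, blocked 0.00323). The cytoskeleton list (0 of 30, 4 with the block; adjusted p = 0.0513, blocked 0.00238) and the matrix list (0 of 21, 1 each way adjusted over the list alone, 5 higher and 1 lower with the block; adjusted p = 0.0979, blocked 0.00235) were called up only with the block. Unblocked camera with an estimated correlation gave 0.892 for each. Striated muscle had 3 higher and 2 lower of 12 adjusted over the list alone (adjusted p = 0.0965), and mammary genes 1 lower of 9 on the same basis (adjusted p = 0.316). Without the block no gene was called in the lists of YAP-TAZ targets (adjusted p = 0.41), integrins (0.807), activating ligands (0.432; 1 lower adjusted over the list alone), MHC class I (0.595), inhibitory ligands (0.342), melanocyte genes (0.461) and mesenchymal genes (0.72), or in p53 targets (0.254), ATF4 targets (0.699) and ribosomal proteins (0.595). With it 2 YAP-TAZ targets and 2 cell cycle genes were higher. Lower with it were 4 immediate early genes, 2 p53 targets and 1 gene each of the activating ligand, ATF4 and interferon lists. The cell cycle had a median of −0.01, a mean of 0.00 and an upward test (adjusted p = 0.943).

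**Figure D3:**
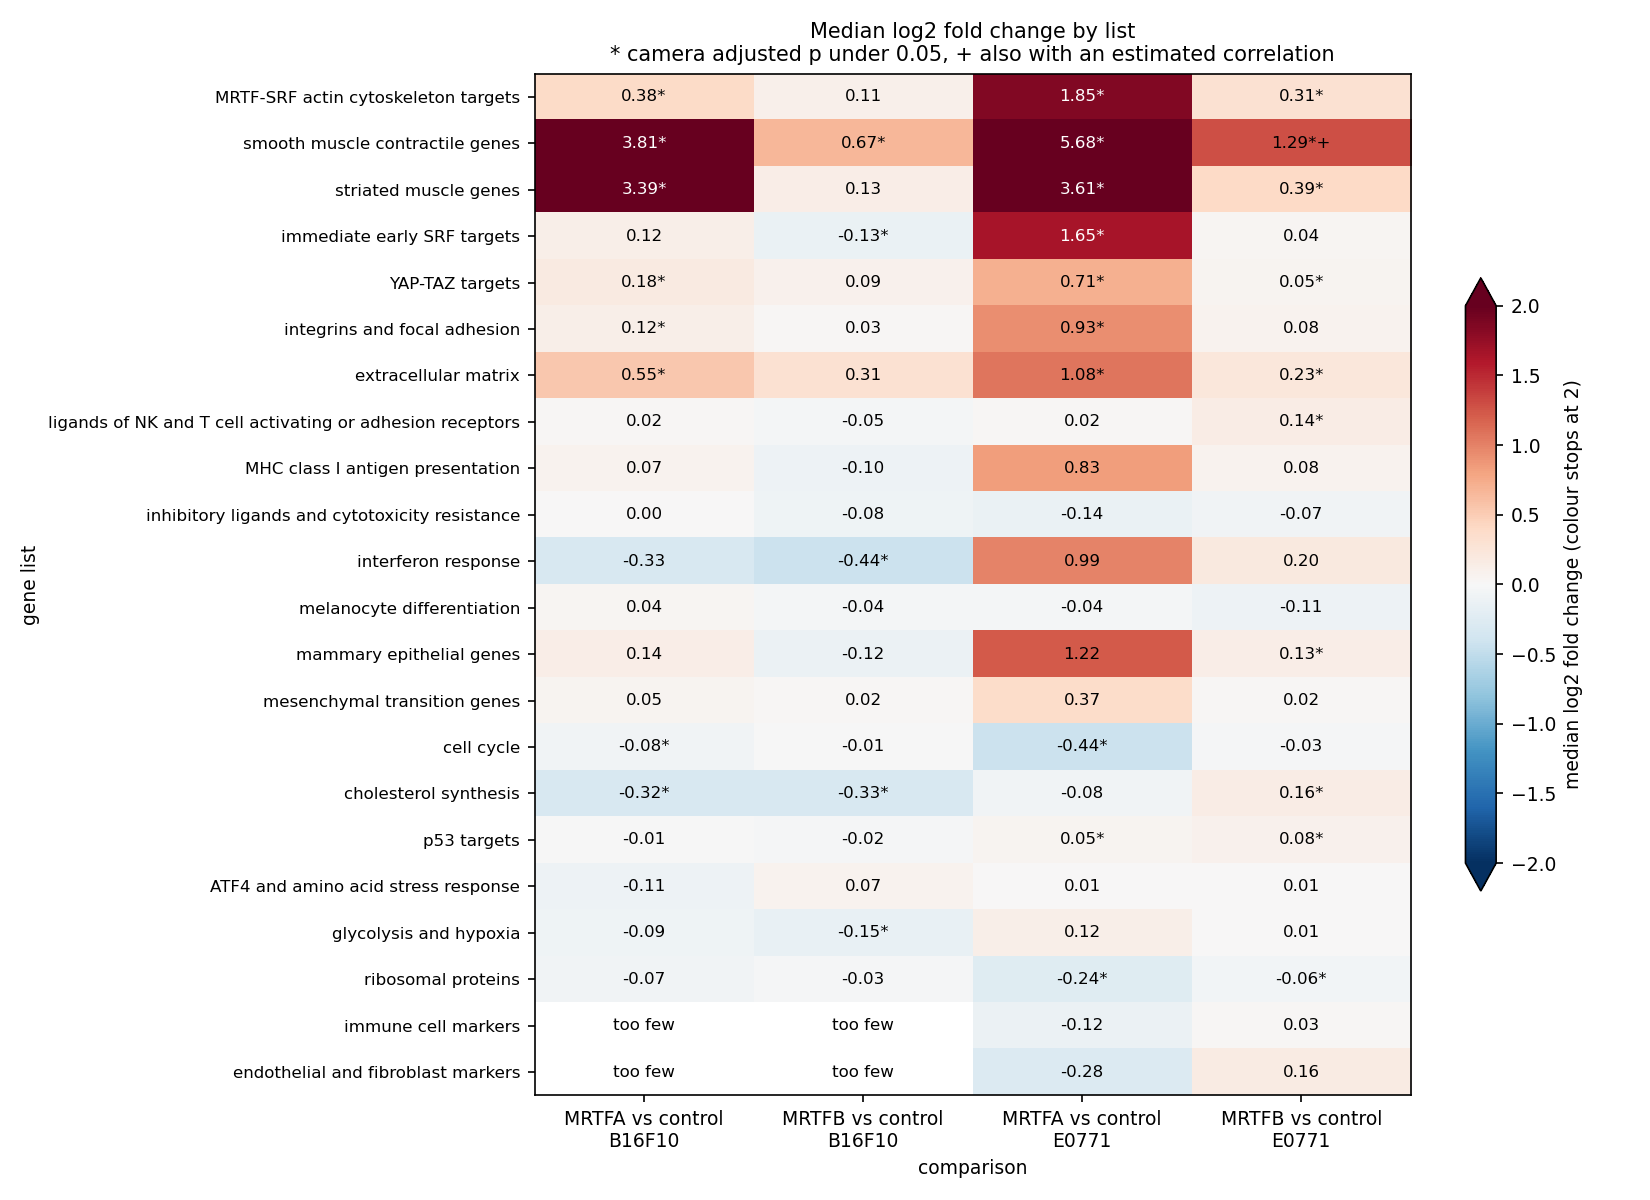
Median log2 fold change (colour and number) of 22 gene lists against the control of their line, in 4 comparisons; an asterisk marks a camera adjusted p under 0.05, a plus sign one that also passed with an estimated correlation. The smooth muscle medians were 3.81 and 0.67 in B16F10 and 5.68 and 1.29 in E0771 for MRTFA and MRTFB.

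**Figure D4:**
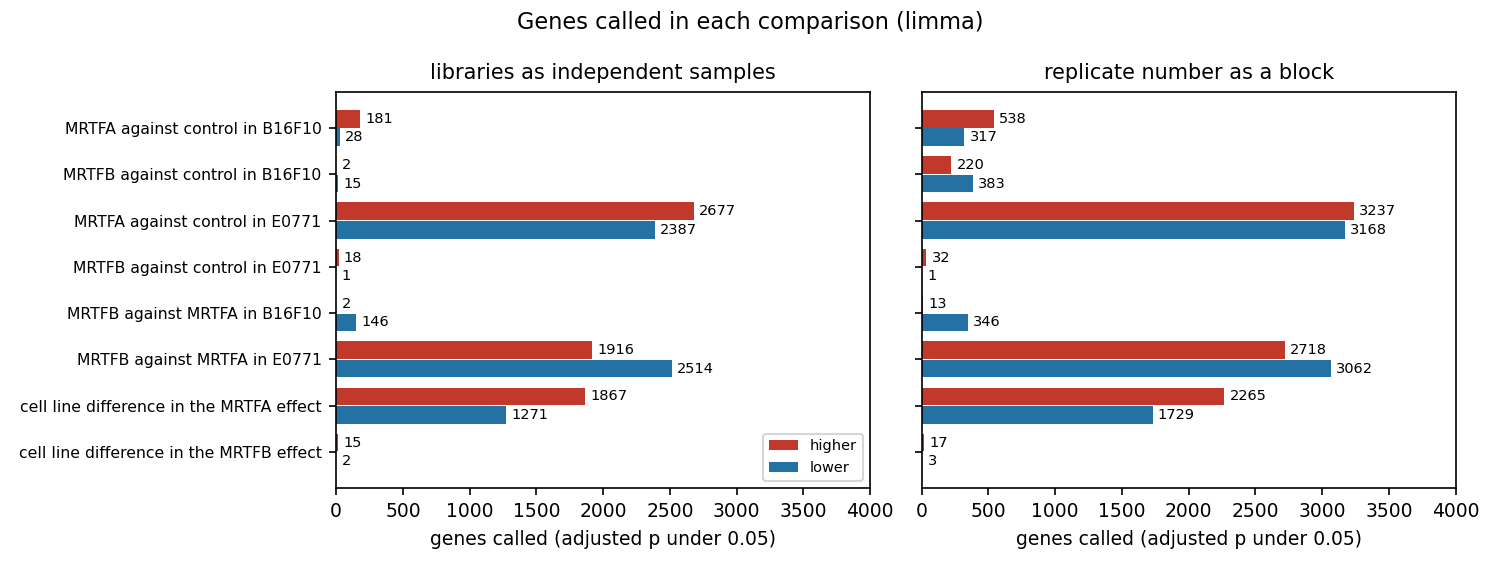
Genes called by limma, higher (red) and lower (blue), in each of the 8 comparisons, with libraries taken as independent (left) or with replicate number as a block (right). MRTFA in E0771 called 2677 higher and 2387 lower, and MRTFB in B16F10 went from 17 genes in all to 603 with the block.

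MRTFB libraries were also set directly against MRTFA libraries, gene by gene. Against control, the transgenes' own genes rose unequally in E0771 and were not called in B16F10. The differences below therefore cannot separate the action of each protein from its dose. In E0771 Actc1 was lower by −12.22 on the log2 scale, Cnn1 by −4.47, Myl9 by −4.51, Ctgf by −3.98, Tagln by −3.41 and Acta2 by −3.40 (adjusted p = 1.86e-07). Mkl1 stood at −3.35 (adjusted p = 5.77e-07) and Mkl2 at 0.87 (adjusted p = 8.01e-05). The tubby gene Tub was at least 860-fold and creatine kinase Ckm at least 597-fold lower with MRTFB, against a limit of 3 reads over that group, and Myh13, with 2 reads, had a ratio of 2004 (95% counting interval 554.4 to 16550). Higher with MRTFB were the lipase gene Lipn (2.52, 105 ± 11.4 against 17.5 ± 3.06, adjusted p = 2.44e-05), F2rl1 (1.97) and Rbp7 (1.80). The calls of Tnfrsf13c (1.88) and Gas7 (1.64) were lost without MRTFB replicate 1 (1.56, 1.46), MRTFB replicate 2 (1.77, 1.41) or MRTFA replicate 3 (1.32, 1.37). Limma called 4430 genes, 1916 higher and 2514 lower with MRTFB; the count was 2914 and 2571 without MRTFA replicates 1 and 2. edgeR called 4248.

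In B16F10 the same comparison called 148 genes, 2 higher and 146 lower with MRTFB (edgeR 132). Actc1 was at −7.65 (adjusted p = 0.00106) and Cnn1 at −7.50 (adjusted p = 0.00177; lost without MRTFA replicate 1, at −7.40). Apol10b had 2.02 against 240 ± 114 (−6.61). Plac8 had 1 MRTFB read and a ratio of 337.6 (95% counting interval 60.2 to 13380), and Dnase1l3 3 reads and a ratio of 128.9 (43.8 to 627.8). Acta2 (−3.14, adjusted p = 0.202, blocked 0.0014), Tagln (−2.35, adjusted p = 0.696, blocked 0.00906), Myl9 (−2.16, adjusted p = 0.47, blocked 0.000199) and Vcl (−0.65, adjusted p = 0.259, blocked 0.00112) passed only with the block, under which 359 genes were called (13 higher, 346 lower). Without MRTFB replicate 3, Acta2 (−4.24) and Tagln (−3.39) passed. Mkl1 stood at −0.32 and Mkl2 at 0.12, both with adjusted p = 1. The calls of Tpm1 (−0.65, adjusted p = 0.0324) and Sgpp2 (1.58, adjusted p = 0.0263) were lost without MRTFB replicates 1 or 2 (Tpm1 −0.59, −0.60; Sgpp2 1.66, 1.43) or MRTFA replicates 1, 2 or 3 (Tpm1 −0.65, −0.75, −0.55; Sgpp2 1.43, 1.70, 1.59). The count was 95 and 94 without MRTFB replicates 1 and 2, and 10, 42 and 16 without MRTFA replicates 1, 2 and 3.

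Genes called with both transgenes were increases in E0771, contractile genes such as Acta2, Tagln and Myl9 among them, and mostly decreases in B16F10. In E0771 17 of the 18 genes higher with MRTFB were also higher with MRTFA, where independent sets would share 3.65. In B16F10 11 genes were lower with both, Rhox5, Dppa2 and Ptpn13 among them, against 0.031 for independent sets, and 1 gene was higher with both. In 100 simulations with the shared control and no transgene effect, the shared counts were 0 and 0.01. Without an effect few genes can be called at all, so these simulated counts are no measure of the excess. Both comparisons of a line use the same 3 control libraries, which cannot be divided, so part of each excess may come from them. Across genes, which are not independent replicates, the log2 changes of MRTFA and MRTFB correlated with r = 0.566 in B16F10 and 0.429 in E0771. The shared control alone gave 0.502 in simulation, a value that does not carry over to data with transgene effects of unequal size. The covariance of the log2 changes was 0.111 in B16F10 and 0.143 in E0771, against 0.0362 and 0.0422 in simulation. The simulations held no deviation common to equal replicate numbers, which the pairing check found, so they leave out that source of agreement. Between lines, which share no library, 155 of the 163 genes higher with MRTFA in B16F10 and tested in both were also higher in E0771 (30.3 for independent sets), and 4 of 16 lower genes were lower in both (3.04). The correlation across 11933 genes was r = 0.606, with a rank correlation of 0.131. For MRTFB no gene was called in both lines by limma. With the block 10 were higher in both (0.454 for independent sets), and r was 0.152, with a rank correlation of 0.002.

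**Figure D5:**
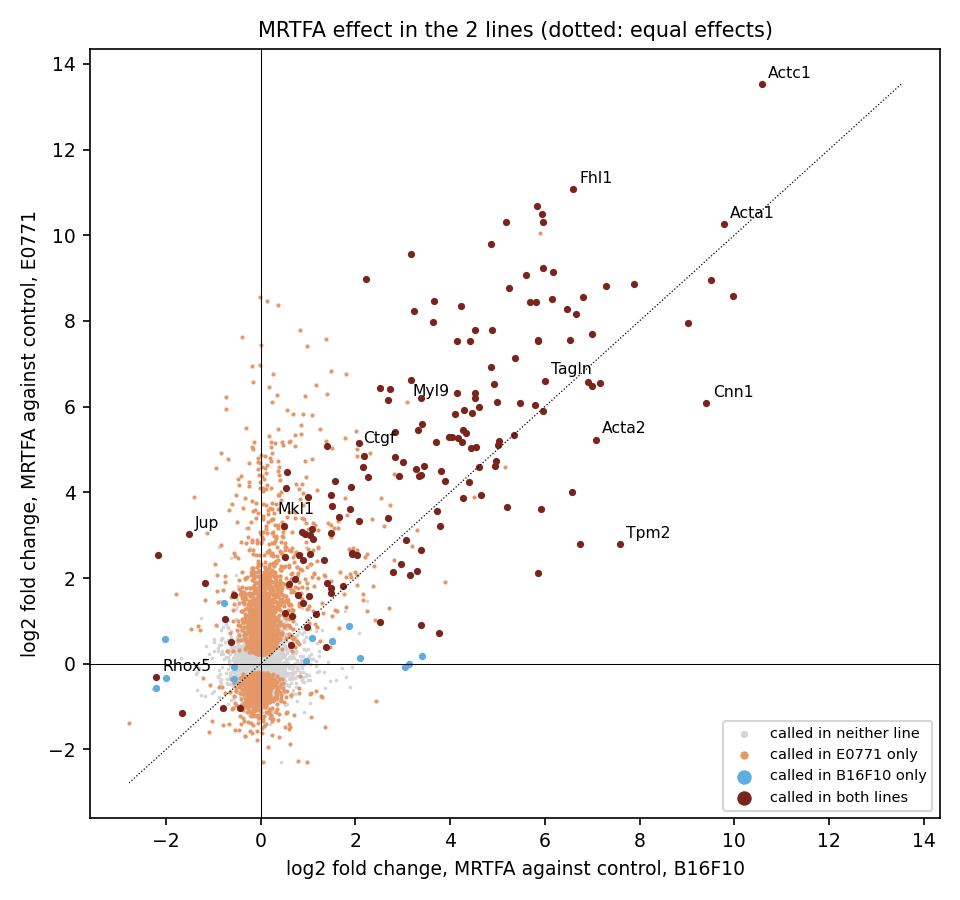
Log2 fold change of MRTFA against control in B16F10 (horizontal) and E0771 (vertical) for 11933 genes tested in both; each point is a gene, coloured by the lines in which limma called it, and the dotted line marks equal effects. Of 163 genes higher in B16F10, 155 were also higher in E0771.

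Changes in the libraries labelled MRTFA were compared between the lines. In a test of the difference over all 18 libraries (E0771 effect minus B16F10 effect), 3138 of 14859 genes passed, 1867 with a higher and 1271 with a lower value in E0771; edgeR gave 2835. Tpm1 (1.73, adjusted p = 6.15e-07), Actb (1.08), Srf (1.76), Vcl (1.52), Ctgf (2.98) and Myl9 (3.03) had larger effects in E0771. Tpm2 (−4.80, adjusted p = 0.00315) and the collagen gene Col3a1 (−3.74, adjusted p = 0.000991) had larger effects in B16F10, where both started lower. Cnn1 (−3.34, adjusted p = 0.0297) did too, but lost its call without E0771 MRTFA replicate 3 (−2.95), E0771 control replicate 2 (−3.10), B16F10 MRTFA replicates 1 or 3 (−3.24, −3.18) or B16F10 control replicates 1 or 2 (−2.96 each). Acta2 (−1.84, adjusted p = 0.183), Tagln (0.60, adjusted p = 0.716) and Cyr61 (1.38, adjusted p = 0.0639) were not shown to differ, though Cyr61 passed without B16F10 MRTFA replicate 3 (1.68) and with the replicate block (adjusted p = 0.000535). Dystrophin Dmd, with 3 control reads in E0771, rose there and stood at 0.37 in B16F10, a difference of 8.01 (adjusted p = 7.80e-09). For MRTFB 17 genes differed, 15 with a higher and 2 with a lower value in E0771, with 16 by edgeR. Jup (2.75, adjusted p = 0.00233), lower in B16F10 at −2.47 and at 0.27 in E0771, kept this call without any single library. Acta2 (−2.10, adjusted p = 0.893, blocked 0.512) and Tagln (−0.47, adjusted p = 1, blocked 0.974) were not shown to differ. The MRTFB count was 3, 5 and 5 without E0771 MRTFB replicates 1, 2 and 3, and 10, 8 and 10 without E0771 control replicates 1, 2 and 3. It was 2 and 4 without B16F10 MRTFB replicates 1 and 2, and 3, 3 and 47 without B16F10 control replicates 1, 2 and 3.

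Melanocyte markers fitted B16F10, where 18 of 19 were higher (median of their control means 10160, against 3.33 in E0771). Mammary markers told the lines apart less clearly. In E0771 13 of 19 were higher, such as Krt8 (6720 against 1.6), and in B16F10 5, Cdh1 and Erbb3 among them, but most were barely expressed (median 11.2 in E0771 and 3.19 in B16F10), and some, such as Krt19, Cldn7 and Tjp3, differed by less than 1 scaled read. Tyrp1 was the most abundant gene in every B16F10 library. Some libraries stood apart from others of their group. In E0771 the mitochondrial share of reads was 0.918, 0.846 and 1.16% in replicate 1 of control, MRTFA and MRTFB, against 0.467 to 0.562% in replicates 2 and 3. In B16F10 replicate 3 had the highest Acta2, Tagln, Myl9 and Ctgf of each group; for Ctgf the control had 795.5, 1037 and 2653 and MRTFB 982.6, 1310 and 5971 scaled reads in replicates 1 to 3.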

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

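The tests of exchanged labels, of an uncounted construct, of dose, of replicate differences, of depth, of MRTFA RNA in an MRTFB library and of TMM scaling were chosen only after the result they bear on was seen; the tests of background reads, of B16F10 RNA and of other splits of the samples were fixed before. The single genes first given were picked out because the effect of a transgene differed between the lines by limma's test of that difference, given as E0771 minus B16F10 on the log2 scale. The uncalled Mkl1, the few calls with MRTFB in B16F10 and the breadth in E0771 were picked out on reading the tables. Only the transgenes, the anchor genes and the largest changes of each comparison were looked at singly.

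The difference in the MRTFA effect passed for 3138 genes. Larger effects in E0771 were found for Mkl1 (3.12), Myl9 (3.03), Vcl (1.52), Srf (1.76), Actb (1.08), Actg1 (0.84), Ctgf (2.98) and Tpm1 (1.73). The widest under the naming rule were Epb41l4b (8.56), Plcb4 (8.33), Fgl2 (8.13), Lpar4 (8.03) and Dmd (8.01). Of the largest MRTFA increases within E0771, Krt20 (6.60), Il1r2 (5.13), Cobl (4.86), Prss46 (4.55), Fhl1 (4.48) and Myh13 (4.36) also differed. Epb41l4b, Fgl2, Dmd, Krt20, Il1r2, Cobl, Prss46 and Myh13 had 1, 0, 3, 3, 3, 1, 0 and 0 control reads in E0771, so their values depend on the pseudocount, and Fgl2 had adjusted p = 1 by edgeR. Larger effects in B16F10 were found for Cnn1 (−3.34), Tpm2 (−4.80), Hopx (−3.95), Col3a1 (−3.74) and Stbd1 (−3.51). Hopx had 0 control reads in B16F10. Stbd1 had 0 in E0771 and adjusted p = 0.864 by edgeR. Cnn1 lost its call without E0771 MRTFA replicate 3 (−2.95), E0771 control replicate 2 (−3.10), B16F10 MRTFA replicates 1 or 3 (−3.24, −3.18) or B16F10 control replicates 1 or 2 (−2.96 each). Genes lower in the B16F10 libraries and less so or higher in E0771 were Gstp2 (2.5), Rhox5 (1.89), Tmsb4x (4.70), Ptpn13 (2.40) and Dppa2 (2.61). Gstp2 and Ptpn13 had 6 and 1 control reads in E0771, too few to be tested in that line alone, so a fall there could not have been seen. F2rl1 (−2.51) and Cda (−2.50) fell in E0771 and differed from B16F10, where F2rl1 had 0 control reads and could not have shown a fall. Among 100 relabelings of the libraries within their lines, 4 called as many genes, the real one included. The highest other relabeling called 3662, and the 6 others that kept the E0771 grouping called 2306 to 3662 while the rest called at most 27. This points to a structure in which the count follows the E0771 effect whatever the B16F10 grouping, so the relabelings do not tell whether chance can be excluded for the difference between the lines.

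The difference in the MRTFB effect passed for 17 genes. Higher values in E0771 were found for Prkar1b (3.38), Tmsb4x (3.08), Thbs2 (3.06), Jup (2.75), Dppa2 (2.57) and Rhox5 (2.19), and a lower one for Pnma5 (−1.60). With the replicate block 15 of the 17 genes were kept, and Prkar1b was not (adjusted p = 0.0532). In 100 relabelings only the real grouping, 1 of them, called as many, and the highest other called 11. The relabelings part the equal replicate numbers that go together within each line, and exchanges of whole pairs were not tested apart, so they do not tell whether chance can be excluded. Dppa2 lost its call without E0771 MRTFB replicate 1 (2.51), B16F10 MRTFB replicate 1 (2.43) or B16F10 control replicates 1 or 2 (2.55, 2.38). Pnma5 lost it without E0771 MRTFB replicates 1, 2 or 3 (−1.60, −1.66, −1.55), E0771 control replicates 1 or 2 (−1.57, −1.58), B16F10 MRTFB replicate 1 (−1.61) or B16F10 control replicates 1 or 2 (−1.53, −1.43). Prkar1b lost it without E0771 MRTFB replicates 1, 2 or 3 (3.59, 3.46, 3.08), E0771 control replicates 1 or 3 (3.08, 3.06), B16F10 MRTFB replicates 1, 2 or 3 (3.31, 3.33, 3.48) or B16F10 control replicates 1 or 2 (3.22, 3.25). Tmsb4x lost it without E0771 MRTFB replicates 1, 2 or 3 (3.05, 3.10, 3.09), E0771 control replicates 2 or 3 (2.92, 3.05), B16F10 MRTFB replicates 1 or 2 (2.69, 2.88) or B16F10 control replicates 1 or 2 (3.07, 3.19). Thbs2 lost it without E0771 MRTFB replicates 1, 2 or 3 (2.97, 2.94, 3.26), E0771 control replicates 1 or 3 (3.10, 2.65), B16F10 MRTFB replicates 1 or 2 (3.03, 2.83) or B16F10 control replicates 1 or 2 (3.05, 2.99). The count was 3, 5 and 5 without E0771 MRTFB replicates 1, 2 and 3, and 10, 8 and 10 without E0771 control replicates 1, 2 and 3. It was 2 and 4 without B16F10 MRTFB replicates 1 and 2, and 3, 3 and 47 without B16F10 control replicates 1, 2 and 3.

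In the B16F10 libraries labelled MRTFA, Mkl1 was not called (log2 0.22, 95% interval −0.18 to 0.63) while the smooth muscle list had a median of 3.81. Exchanged MRTFA and control labels would have put that median of 3.81 below 0, and a construct common to both lines that escaped the Mkl1 count would not have given the rise of 3.34 in E0771, so the tables argue against both. Exchanged MRTFA and MRTFB labels would not account for the uncalled Mkl1, which would then have risen in the libraries labelled MRTFB. There it stood at −0.10 against control (95% interval −0.50 to 0.30). Mkl2 cannot tell exchanged labels from correct ones, because it differed by only 0.12 between these groups (adjusted p = 1). A lower transgene dose in B16F10 may be the cause, since 20 of the 30 cytoskeleton targets had a larger effect in E0771 and 1 a larger effect in B16F10 (median difference 1.19), although Cnn1 and Tpm2 went the other way. A construct that differs between lines and a biological difference between the lines, which the design names, also stay open and were not tested.

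With MRTFB in B16F10, 17 genes were called although single genes differed severalfold, such as Acta2 at 3.93. The libraries' depth, 0.976 of the control's, argues against low depth as the cause. A difference shared by equal replicate numbers may be part of it: 603 genes passed with the block. RNA of an MRTFA library in MRTFB replicate 3 would bring the same share of every MRTFA-induced gene. Against MRTFA replicate 3, 11 of 21 such genes lay within 2-fold of their median share of 8.49%, just over the bound set. However, among genes at 1000 or more in MRTFA replicate 3, Cnn1 allows a share of only 1.58% (1.21% for the less abundant Apol10b), which argues against such RNA as the source of Acta2 (35.8%) and Tagln (64.7%) and against a common share near 8.49%. A share no larger than these stays open. A true variation among replicates in how strongly MRTFB acted stays open and was not tested apart from these.

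The breadth of the E0771 MRTFA response, 5064 genes, was set against 3 technical sources. Background reads would have raised silent genes alike, but 10.8% (303 of 2816) reached a value of 10 and the median stayed at 0.99, against 1 gene reaching 10 with MRTFB. B16F10 RNA would have brought that line's abundant transcripts, but the median of 118 genes silent in E0771 and at 1000 or more in B16F10 was 0.0508% of the B16F10 level. Reads taken up by a few genes would make others look lower, and such calls would be lost under TMM scaling. Under TMM 2139 genes were still called lower, against 2387 without it and 2753 under upper-quartile scaling. The deposited values were already divided by DESeq size factors. TMM on top moved the median log2 change only from −0.024 to 0.006, so it had little to change and does not decide this. The 2804 genes called higher under TMM do not bear on this. The tables argue against background reads and B16F10 RNA. The 10 most abundant genes took 6.96 to 7.55% of reads in E0771 MRTFA libraries and 4.79 to 4.95% in controls. Reads taken up by a few genes would lower all others alike, and the median change was −0.024. That argues against this source for the 161 genes lower by at least 2-fold, and leaves it undecided for smaller decreases. A direct or secondary response of the cells to MRTFA, in a line where Mkl1 rose by 3.34, remains a hypothesis found and tested on the same data. Which of the genes are direct targets was not tested.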

How the results depend on the processing

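edgeR with the block and the fits without every group's replicate 1 or 3 were chosen after the data were seen; all other alternatives were fixed before the data were examined. No named gene reversed under any of them. Of 494 named-gene results, 488 kept their call under edgeR (6 were lost), 488 under TMM (6 lost), 492 under upper-quartile scaling (2 gained), 491 without a filter (1 lost, 2 gained) and 493 under each pseudocount (1 lost). Under DESeq2 445 of 488 kept it (2 lost, 41 gained), with the block 409 of 494 (1 lost, 84 gained), with edgeR and the block 412 (5 lost, 77 gained), with a minimum of 50 448 of 457 (9 lost), with all 18 libraries 413 of 451 (21 lost, 17 gained), with the 6 libraries compared 421 of 440 (13 lost, 6 gained) and with the 12 compared 36 of 43 (5 lost, 2 gained). Of 88 list results 55 kept their call with an estimated correlation and 33 lost it; fry kept 65 (19 lost, 4 gained), the block 76 (3 lost, 9 gained), TMM 87 and upper-quartile scaling 86.

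The number of genes called moved by more than 1.5 times as follows. For MRTFA in B16F10 (209) it was 324 without a filter, 107 with a minimum of 50, 357 with DESeq2, 855 with the block, 421 with all 18 libraries and 859 with edgeR and the block. For MRTFB in B16F10 (17) it was 5 with a minimum of 50, 6 with TMM, 179 with DESeq2, 603 with the block, 57 with all 18 libraries, 9 with the 6 compared and 546 with edgeR and the block. For MRTFB in E0771 (19) it was 51 with DESeq2, 33 with the block, 5 with the 6 libraries and 30 with edgeR and the block. For MRTFB against MRTFA in B16F10 (148) it was 260 without a filter, 71 with a minimum of 50, 359 with the block, 322 with all 18 libraries and 354 with edgeR and the block. For the line difference in MRTFB (17) it was 28 with a pseudocount of 5, 41 with DESeq2 and 3 with 12 libraries. A minimum of 50 tests fewer genes and the smaller fits have fewer samples; for the rest the cause was not tested. Among the genes and lists printed for paired comparisons, the block changed no other call than those given beside them. In comparisons not read as paired it called 6405, 3994 and 20 genes (MRTFA in E0771 and the line differences), and in MRTFA in E0771 it called the MHC class I (0.000834), interferon (0.000125) and mesenchymal lists (0.0272) up. The 20 genes of the MRTFB line difference held 15 of the 17 called without the block. YAP-TAZ targets with MRTFA in B16F10 had adjusted p = 0.0539 under TMM and 0.0535 under upper-quartile scaling.

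Leaving out 1 library, or replicate 1 or 3 of every group, gave 0 to 324 genes for MRTFA in B16F10, 0 to 224 for MRTFB in B16F10, 2850 to 4621 for MRTFA in E0771, 6 to 15 for MRTFB in E0771, 0 to 213 and 2374 to 4392 for MRTFB against MRTFA in B16F10 and E0771, and 1040 to 3040 and 0 to 52 for the line differences in MRTFA and MRTFB. Each lowest value but that of MRTFB in B16F10, also reached by single libraries, was found only without every group's replicate 1, with fewer samples. The 0 counts are limma's; with all libraries limma had 1272 and 1199 genes at an unadjusted p under 0.05 for MRTFA and MRTFB in B16F10, 586 for MRTFB against MRTFA there and 811 for the line difference in MRTFB, and edgeR called 213, 16, 132 and 16. Of the lists, the melanocyte list with MRTFB in B16F10 reversed without every group's replicate 3 (adjusted p = 0.0205, up; 0.072 without replicate 1), and ribosomal proteins with MRTFB in E0771 reversed without replicate 1 (adjusted p = 0.523, up; 0.00267 without replicate 3). Depth limits genes with few reads: a library's 0 allows 0.081 to 0.109 CPM.

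Exchanging samples between the groups of a comparison gives 10 splits of 6 libraries, too few for a share under 0.05. In each comparison within a line the real split was the only one, 1 of 10, to call as many: 209, 17, 5064, 19, 148 and 4430 genes. The highest other called 1 for MRTFB against MRTFA in B16F10 and 0 elsewhere, and the 3 other splits that part all pairs called 0 by limma.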

Other observations

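The family tests in this part were chosen only after the data were examined; the test of genes lower with both transgenes was fixed before its result was seen. Genes were grouped into families by symbol and the called genes counted in each with Fisher's exact test (98 tests in 25 families, adjusted together). The test takes genes as independent, so its p-values are too small where genes of a family move together. With MRTFA in E0771 the ribosomal list went from camera adjusted p = 0.00505 to 0.623 with an estimated correlation. Expected counts apply the share called among all tested genes, whatever their level of expression. Families of abundant or of weakly expressed genes may depart from them for that reason, which was not tested.

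With MRTFA in E0771, genes of LIM-domain and leiomodin families, which organise thin filaments and the Z-disc, rose as a set. Lmod1, Lmod3, Csrp1, Csrp2, Fhl1, Fhl2, Fhl3, Fhl4, Pdlim2, Pdlim3, Pdlim4, Pdlim5, Pdlim7 and Tmod1 were higher, 14 of 17 tested where 3.45 would be expected (adjusted p = 3.49e-06), and Pdlim1 was lower. In the B16F10 libraries labelled MRTFA 5 of 17 were higher (Pdlim3, Lmod3, Lmod1, Fhl1 and Pdlim5; 0.228 expected, adjusted p = 3.61e-05). Potassium channel genes had 10 of 17 higher in E0771, such as Kcnmb1, a regulatory subunit of a calcium-activated channel of smooth muscle, Kcnv2, Kcnip3, Kcnq1 and Kcnh2 (3.45 expected, adjusted p = 0.00678); none was lower, but 2 were under upper-quartile scaling. Collagen genes had 14 of 29 higher, such as Col4a1, Col4a2, Col6a3, Col12a1 and Col3a1, and 2 lower (5.89 expected, adjusted p = 0.00739). Tropomyosins and troponins had 7 of 11 higher: Tpm1, Tpm2, Tpm4, Tnnt1, Tnnt2, Tnnt3 and Tnni1 (2.23 expected, adjusted p = 0.021). More ribosomal protein genes of both compartments were called lower than expected, though most were not called. Of 82 cytosolic ones, such as Rpl14, Rpl3 and Rpl22, 34 were lower (14.8 expected, adjusted p = 1.81e-05) and none higher by limma or under TMM and upper-quartile scaling. Of 78 mitochondrial ones, such as Mrpl42, Mrpl19 and Mrps6, 33 were lower (14.1 expected, adjusted p = 1.81e-05) and 3 higher. Zinc finger genes were less often lower, with 25 of 303 where 54.8 would be expected (adjusted p = 3.08e-05), while the 49 higher, where 61.5 would be expected, did not pass (adjusted p = 0.258). These family directions held under TMM and upper-quartile scaling.

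In B16F10 with the block, 190 genes were lower with both transgenes, Rhox5, Dppa2 and Ptpn13 among them. Their MRTFB change was a median of 1.13 times the MRTFA change (quartiles 0.969 to 1.29), and 2 of them differed between the transgenes. The 116 genes higher with both had a median ratio of 0.915 (quartiles 0.596 to 1.08), and 27 differed. A difference of the control libraries from both transgene groups, whatever the transgene, would put the ratio of the shared decreases near 1, where 1.13 lies. The ratio of 0.915 for the shared increases lies near 1 as well. The genes were chosen for passing in the same direction in both comparisons, which share their controls, and both facts pull such a ratio toward 1. It therefore cannot tell a difference of the controls from a response shared by MRTFA and MRTFB, and both stay open.

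Acta2 made up 2.21, 2.36 and 1.99% of all reads in E0771 MRTFA replicates 1 to 3 and was the most abundant gene there, while Eef1a1 was the most abundant in the other E0771 libraries.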
